A study of Mus musculus with 8 samples.

How the data were processed

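Small RNA sequencing libraries of mouse liver were analysed: 1 whole-liver pool of 3 RNA samples per diet and 3 mitochondrial libraries per diet, 8 libraries in all. Per the labels' protocols, mice of 8 weeks received food ad libitum (AL) or a restricted diet (CR) for 12 weeks, with a restriction of 20% in the first week and 40% in the other 11. Whole-liver RNA was extracted directly with Trizol, and mitochondria were first isolated by differential centrifugation as mitoplasts, per the labels' protocols. Groups were taken from the labels, and all 8 libraries were used.

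The deposited values are RPM, each library's reads scaled to a total of 1000000, of the reads that the authors assigned to the listed miRNAs, 1 table per library with miRNA names at 0 left out. The tables' column names say tpm, and the values of each deposited RPM column sum to 1000000 with no scaling for length. Reads were mapped with Bowtie against the mouse genome build mm9, per the submitters' processing notes, which give no version. How names were assigned, which mismatches and multiple hits were allowed, whether strand was used in counting and how unannotated candidates were found are not stated. Each deposited RPM value was a whole multiple of the smallest in its library (100% of values, within 0.01 read), so reads per miRNA were recovered by division. The depth per library is given with the results, and 3 reads, the floor used for a level of 0, were worth 0.925 and 1.23 RPM in the pools and 1.90 to 2.80 RPM in the mitochondrial libraries.

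The choices of tests, lists, named miRNAs and alternatives called planned were made before the data were examined. That plan used an edgeR test if the files held counts and limma-trend if they held normalized values. Since the files hold RPM, limma-trend (limma 3.58.1, R 4.3.3) was run on log2(RPM + 1) for miRNAs with at least 1 RPM in at least 3 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. edgeR 4.0.16 (quasi-likelihood test), limma-voom and DESeq2 1.42.0 were run on the recovered reads as alternatives, and edgeR with TMM called 5 miRNAs in the mitochondrial diet comparison. CR was compared with AL in the 6 mitochondrial libraries. Mitochondria were compared with whole liver over all 8 libraries with diet as a term, and the interaction of diet and fraction was tested over all 8. In both of these the 2 pools are assumed to vary like the mitochondrial libraries. For the whole-liver pools, ratios of RPM are given for miRNAs with at least 10 RPM in 1 of them, without a p-value. Exact 95% Clopper-Pearson intervals, conditional on the reads of both pools, are printed for some of them. Counts, list medians and ranking of the pools used ratios with 1 RPM added, and printed folds and intervals used plain ratios. The share of miR-122, both arms together, was compared with an exact two-sided permutation test. Correlations across miRNAs used 100000 permutations (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, and matplotlib 3.10.9 for the plots). Of the 2 relations across miRNAs computed for the results, only that of the pools with mitochondria was tested.

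The 19 miRNA lists, matched by miRNA name with any arm, were markers of hepatocytes, erythroid cells, leukocytes with Kupffer cells, endothelium, stellate cells with fibroblasts, bile duct epithelium, muscle, pancreas and neurons. The others were miRNAs named in mitochondria by earlier work, miRNAs of lipid and glucose metabolism, ageing and senescence miRNAs, the let-7, miR-30, miR-29 and miR-181 families, the miR-17-92 clusters, the Dlk1-Dio3 region and the miR-10, miR-99 and miR-100 relatives. Lists with at least 3 tested members (18 in each comparison) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. In whole liver, list medians were placed among 10000 random lists.

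Named miRNAs followed a fixed rule. In mitochondria these were the miRNAs past the threshold, others with the smallest p up to 20 in all, and the 5 most abundant under AL. Against whole liver they were the 10 largest changes in each direction that went the same way in both diets and the 5 most abundant in each pool. In the pools they were the 10 largest ratios in each direction, for the interaction the 5 smallest p, and for each list up to 4 members by p. Members of a list that passed the threshold, the miRNAs in the closing section, and some that did not pass beside those named, were named in addition, after their values were seen.

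Hairpin positions come from a search of each mature sequence in the hairpin transcripts of GENCODE M21 (GRCm38), not from the authors' mm9 alignment. Of 823 annotated miRNA names 821 matched, and none of the 39 unannotated names (novel_ followed by a number). Mature sequences were also searched in 37 mitochondrial transcripts and in other annotated small RNAs: 2 names matched a mitochondrial tRNA and 25 another small RNA. The other small RNAs were those annotated as rRNA, snoRNA, snRNA, small Cajal body RNA or miscellaneous RNA, without nuclear tRNAs. A name without a match may thus still be a piece of another RNA. For 91 names another name has a near-identical sequence, so their reads may be shared.

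The fits were tested on simulated reads with 200 miRNAs changed at once, of a median of 405.5 tested in the diet comparison. Recovery with fewer changed miRNAs, where the adjusted threshold is stricter, was not simulated and may be lower. In the mitochondrial diet comparison 24.9% of 2-fold, 73.3% of 4-fold and 91.0% of 8-fold changes were recovered, and against whole liver 22.3%, 72.4% and 90.5%. Alternatives covered scaling (DESeq2 size factors, upper quartile factors, TMM, miR-122 left out), filters, pseudocounts of 0.1 and 10, the tools above, a replicate block, robust moderation and each mitochondrial library left out. TMM scaling of RPM, edgeR with TMM, limma with robust moderation, the minimum of 100 reads in the pools, pool ratios with nothing added and the antisense names left out were added after the data were seen. Summing repeated names was planned and did not apply, since no table repeats a name. Library size alone is the deposited RPM scale itself and was run in edgeR only. Other sequencing data of the series, such as raw reads, were not used here.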

Results

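Small RNA was sequenced from the livers of male C57BL/6J mice fed ad libitum (AL) or under caloric restriction (CR) for 12 weeks, to compare miRNA levels between the diets in whole liver and in purified liver mitochondria. Whole liver was represented by 1 library per diet, each made from a pool of 3 RNA samples. Mitochondrial RNA was represented by 3 libraries per diet. The whole-liver pools held 2431564 (AL) and 3242002 (CR) miRNA reads, recovered as whole numbers from the deposited RPM, the reads scaled to a library total of 1000000. The AL mitochondrial libraries held 1083328, 1095018 and 1422418 reads and the CR mitochondrial libraries 1200984, 1577691 and 1070762. A single read was worth 0.308 to 0.934 RPM. The 8 libraries listed 862 miRNA names in all, and the first principal component, with 52.6% of the variance, separated mitochondria from whole liver. Pearson's r of log2 values within the mitochondrial groups lay between 0.967 and 0.977. Over all pairs of mitochondrial libraries it lay between 0.964 and 0.977, and pairs of different diets reached 0.974 (AL replicate 3 with CR replicate 3). Libraries of the same diet were thus hardly closer to each other than to those of the other diet. The labels do not say whether the mitochondrial replicates came from separate animals, so p-values measure the spread between these libraries. Intervals and floors cover counting error only.

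The libraries were dominated by liver miRNAs. The hepatocyte miRNA miR-122 (both arms) took 41.6% ± 3.67 (SD, n = 3) of the reads in AL mitochondria and 45.5% ± 17.8 (SD, n = 3) in CR mitochondria, with shares of 53.3%, 25.2% and 58.1% in the CR replicates. In the pools its share was 25.5% (95% Clopper-Pearson interval 25.4% to 25.6%) under AL and 26.3% (26.3% to 26.4%) under CR. The CR minus AL difference in mitochondria was 3.91 percentage points, with an exact two-sided permutation p of 0.8, where 0.1 is the smallest p that 3 against 3 libraries allow. Without CR replicate 3 the difference was -2.38 points, and without CR replicate 2 it was 14.1 points.

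The main question of the series was which mitochondrial miRNAs differ between the diets. In liver mitochondria, miR-802-5p rose and miR-199a-3p fell under CR. miR-802-5p, a miRNA known to be raised in obese liver and to impair glucose metabolism there, rose from 59.4 ± 56.3 RPM (SD, n = 3) under AL to 366 ± 112 RPM (SD, n = 3) under CR, a 7.86-fold change as fitted on log2(RPM + 1). miR-199a-3p, a miRNA best known from mesenchymal cells, fell 3.11-fold by the same fit, from 1889 ± 351 RPM to 602 ± 77.0 RPM. For both, all 3 CR libraries lay on the same side of all 3 AL libraries.

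By limma-trend, these were the 2 of 391 tested miRNAs past an adjusted p of 0.05, with 52 at an unadjusted p under 0.05. The log2 fold change of miR-802-5p was 2.97 (SE 0.51, adjusted p = 0.00768; 3.71 without AL replicate 1 and 2.39 without AL replicate 3) and that of miR-199a-3p -1.64 (SE 0.32, adjusted p = 0.0141). The miR-802 hairpin lies on chromosome 16 at 93369720 to 93369816 (GRCm38, plus strand) with no annotated gene on that strand around it. Mature miR-199a-3p is made from 3 hairpins, on chromosome 9 at 21496495 to 21496564, on chromosome 1 at 162217814 to 162217923 within an exon of Dnm3os, and on chromosome 2 at 32318460 to 32318569 (Mir199b), and its reads cannot be assigned to 1 of them. The 1 higher and 1 lower call became 4 higher and 1 lower with DESeq2 size factors or TMM factors, 2 higher and 4 lower with upper quartile factors, and 3 higher and 1 lower with miR-122 left out. Both miRNAs were called in the same direction in each of those 4. The median log2 fold change of all tested miRNAs was -0.17 on the deposited scale and 0.03 with DESeq2 size factors. Across 25 alternatives the adjusted p of miR-802-5p ranged from 8.5e-13 to 0.133. Its call was lost without AL replicate 2 (adjusted p = 0.133), CR replicate 1 (0.118) or CR replicate 2 (0.0714), with robust moderation in limma (0.0597), and in edgeR with upper quartile factors (0.0639) or library size alone (0.115). That of miR-199a-3p ranged from 0.000493 to 0.158 and was lost without AL replicate 2 (0.0773) or 3 (0.158) and without CR replicate 1 (0.118), 2 (0.0714) or 3 (0.108).

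The next 18 miRNAs by p did not pass. miR-146a-5p, which dampens NF-kappaB signalling, averaged 9595 RPM under AL and 3600 RPM under CR (log2 fold change -1.43, SE 0.35, adjusted p = 0.0730). miR-199a-5p, from 2 of the 3 hairpins of miR-199a-3p (not Mir199b), averaged 342 and 146 RPM (-1.25, adjusted p = 0.0736), and part of its reads may belong to the near-identical miR-199b-5p. The other arm of the miR-802 hairpin, miR-802-3p, averaged 10.5 RPM under AL and 42.2 RPM under CR (2.27, SE 0.58, adjusted p = 0.0736; 2.95 without AL replicate 1 and 1.53 without AL replicate 3). miR-31-3p (9.08 and 32.2 RPM), miR-6240 (10.7 and 34.9 RPM) and miR-96-5p (6.64 and 21.2 RPM) had log2 fold changes of 1.72, 1.62 and 1.67, with adjusted p of 0.0730, 0.0736 and 0.108. Of the alternatives that tested them, 13 of 24 called miR-31-3p, 10 of 24 miR-6240 and 10 of 24 miR-802-3p, 8 of 25 miR-146a-5p, 5 of 25 miR-199a-5p, 5 of 25 let-7d-3p, 5 of 24 miR-96-5p and 1 of 25 miR-7a-5p. The p53 target miR-34a-5p averaged 87.4 RPM under AL and 33.4 RPM under CR (-1.30, adjusted p = 0.118). For let-7d-3p the log2 fold change was -1.22, for miR-7a-5p -1.24, for miR-497a-5p -1.25, for miR-185-5p -0.99, for let-7c-1-3p -1.73 and for let-7b-5p -0.96, with adjusted p from 0.0772 to 0.173. Of these let-7c-1-3p rests on very few reads, 2, 4 and 5 in the AL and 0, 1 and 0 in the CR mitochondrial libraries. Its log2 fold change ranged from -3.94 to -0.35 over the alternatives. miR-7a-5p has a near-identical name, miR-7b-5p. The sequence of miR-1839-3p (-1.53, adjusted p = 0.108) is also found in an annotated small Cajal body RNA. The hairpin of miR-6481 (-1.88, adjusted p = 0.127) is annotated on chromosome 3 at 99199344 to 99199453 (GRCm38), its mature sequence is also found in the mitochondrial tRNA gene mt-Tf, and its AL level was 176 ± 182 RPM (SD, n = 3) against 32.5 ± 10.1 RPM under CR. Its log2 fold change was -2.61 without AL replicate 1 (adjusted p = 0.000355) and -1.04 without AL replicate 2 (0.419), and 3 of 24 alternatives called it. Of the unannotated names, novel_353 and novel_226 had log2 fold changes of 1.74 and 1.80 and novel_315 of -1.90 (-1.11 without CR replicate 1). These rest on few reads. For novel_226 they were 1, 0 and 1 in the AL and 2, 13 and 5 in the CR mitochondrial libraries, and its log2 fold change ranged from 0.47 to 3.25 over the alternatives. In 76 of the 391 tested miRNAs (19.4%) the 3 CR and the 3 AL libraries did not overlap, where chance gives 10% on average. All miRNAs share the same 6 libraries and their scale, so the share can lie far from 10% by chance. Its spread over other splits was not computed.

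The 5 most abundant miRNAs of AL mitochondria did not pass either. miR-122-5p averaged 415777 RPM under AL and 454962 RPM under CR (log2 fold change 0.04, SE 0.50), miR-148a-3p 101350 and 121344 RPM (0.23), miR-21a-5p 81553 and 57566 RPM (-0.48), and miR-192-5p 53938 and 39494 RPM (-0.56). miR-30a-5p had a log2 fold change of -0.08, which was above 0 under 10 other scalings or tools, at up to 0.26 with DESeq2.

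**Figure D1:**
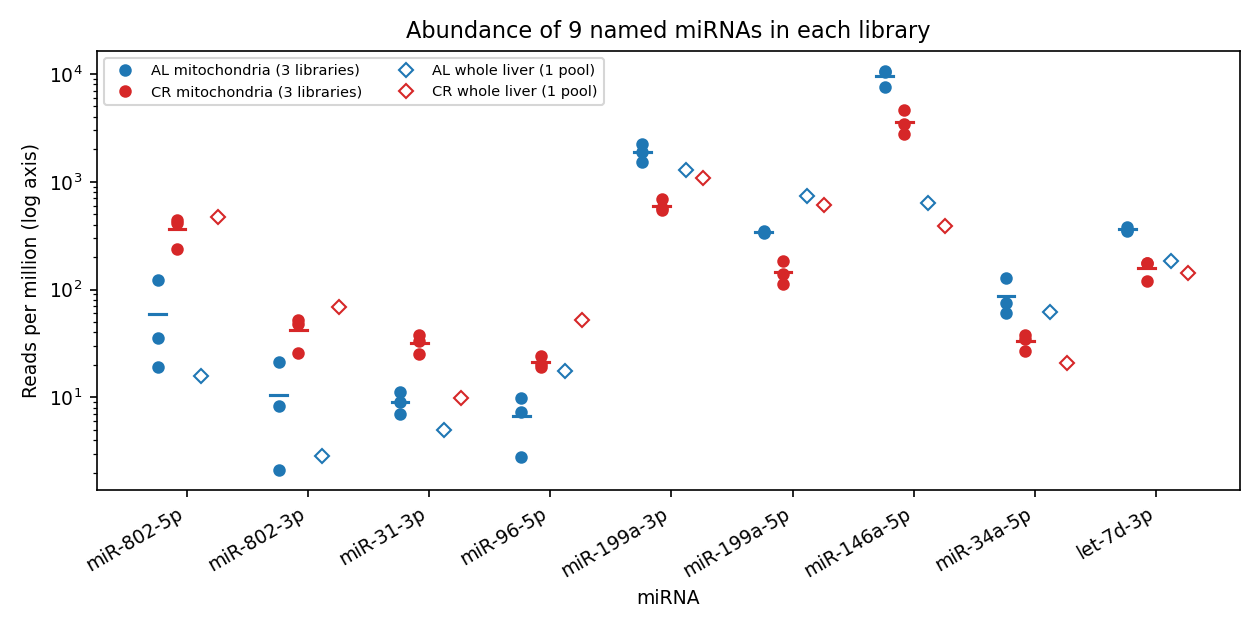
RPM (log axis) of 9 named miRNAs in each library, of which miR-802-5p and miR-199a-3p passed the diet test in mitochondria. Circles are the 3 mitochondrial libraries of each diet, bars their means and diamonds the 1 whole-liver pool per diet; the 3 CR mitochondrial values of miR-802-5p (419, 441 and 237 RPM) lie above the AL values (124, 35.6 and 19.0 RPM).

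Among the cell type lists, that of stellate cells and fibroblasts passed camera with the diet at the preset correlation (downward, adjusted p = 0.0483), but not at an estimated correlation (adjusted p = 0.863), and 8 of the 10 splits of the 6 libraries gave at least 1 list. Of its 9 measured members 1 fell (miR-199a-3p) and 8 did not pass, and adjusted over the list alone 2 fell, miR-199a-3p and miR-199a-5p. The median log2 fold change was -0.58, or -0.41 relative to the median of all tested miRNAs, and it stayed below 0 in all 13 alternatives run (-0.74 to -0.34). Among these, camera at an estimated correlation, fry and the replicate block cannot change the median. miR-214-3p had -0.78 and the abundant smooth muscle miRNA miR-143-3p -0.39. The call was also lost with DESeq2 size factors (adjusted p = 0.0865), with TMM factors (0.0797), with the most abundant arms alone (0.208), and without AL replicate 1 (0.0637), 2 (0.0675) or 3 (0.143) or CR replicate 2 (0.0903) or 3 (0.0532).

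The other cell type lists did not pass camera. In the leukocyte and Kupffer cell list none of 9 members passed by limma, 3 stood at an unadjusted p under 0.05, 1 fell adjusted over the list alone (miR-146a-5p), and the median was -0.56 (adjusted p = 0.426). Its member miR-142a-3p shares its read numbers with an antisense name. The hepatocyte list had 1 of 16 members past the threshold, miR-802-5p, with miR-802-3p added when adjusted over the list alone. Its median (-0.02) and mean (0.21) differed in sign (adjusted p = 0.426). None of the 6 bile duct epithelial members (median 0.32, adjusted p = 0.144), 4 endothelial members (-0.11, 0.840), 4 muscle members (-0.22, 0.840), 3 neuronal members (-0.51, 0.840) or 5 erythroid members (-0.39, 0.898) passed, also when adjusted over the list alone, with 1, 0, 0, 0 and 0 members at an unadjusted p under 0.05 by limma. In the muscle list miR-1a-3p and miR-1b-5p, and in the endothelial list miR-126a-5p and miR-126b-3p, are antisense to each other with near-equal reads, as are miR-486a-3p and miR-486a-5p in the erythroid list, and miR-129-5p of the neuronal and miR-136-5p of the Dlk1-Dio3 list to other names. With miR-486b-3p, 3 of the 5 erythroid members held similar reads (171, 174 and 165 in all) and set the negative median, whereas miR-451a had 0.16 and miR-144-3p 0.52. The pancreas markers had too few tested members for camera. CR replicate 2 held 100 reads of miR-375-3p (63.4 RPM) and 52 reads of miR-217-5p (33.0 RPM), against 1 to 8 and 0 to 5 reads in the other libraries. The remaining pancreas markers were not raised in it: miR-216a-5p and miR-216b-5p had 2 reads each and miR-216b-3p 0, with up to 2 reads of each elsewhere. Without that library 0 miRNAs passed by limma in the diet comparison, with 55 at an unadjusted p under 0.05, and no other tool was run without it. The log2 fold changes stayed at 2.81 for miR-802-5p and -1.61 for miR-199a-3p, and 0 miRNAs also passed without AL replicate 2 or CR replicate 1.

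Of the functional lists and families, none passed camera with the diet. The list of lipid and glucose metabolism had 1 riser, miR-802-5p, among 24 members (median -0.17, adjusted p = 0.840), and adjusted over the list alone 2 rose (both miR-802 arms) and 1 fell (miR-34a-5p). None of the 21 members that earlier work has named in mitochondria passed (median -0.22, adjusted p = 0.840), and adjusted over the list alone miR-146a-5p and miR-34a-5p fell. The same pair fell, adjusted over the list alone, among the 16 ageing and senescence miRNAs (median -0.11, adjusted p = 0.840). Of 19 let-7 family members none passed, with let-7d-3p lower when adjusted over the list alone (median -0.42, adjusted p = 0.144). No member passed, also when adjusted over the list alone, among the 13 miR-10, miR-99 and miR-100 relatives (median -0.43, adjusted p = 0.426), the 6 of miR-181 (-0.36, 0.840), the 11 of miR-30 (-0.00, 0.840), the 7 of miR-29 (0.19, 0.840), the 16 of the imprinted Dlk1-Dio3 region (-0.06, 0.841) and the 13 of the miR-17-92 clusters (0.01, 0.898). At an unadjusted p under 0.05 by limma were 3 of the miRNAs named in mitochondria, 2 ageing, 5 let-7, 0 miR-10 relatives, 1 miR-181, 2 miR-30, 0 miR-29, 0 Dlk1-Dio3 and 3 miR-17-92 members. With a negative mean, the camera direction was upward for the miR-30, miR-29, endothelial, lipid and glucose, Dlk1-Dio3, miR-17-92 and erythroid lists.

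The whole-liver pools were compared to see how diet changes miRNA levels in the tissue as a whole. Both arms of miR-802 stood far apart from the rest. miR-802-5p was at 15.6 RPM (38 reads) in the AL pool and 470 RPM (1525 reads) in the CR pool, a 30.1-fold ratio (95% exact interval 21.8 to 42.7). miR-802-3p was at 2.88 and 69.4 RPM, a 24.1-fold ratio (11.5 to 60.7). Next were miR-96-5p (2.97-fold higher in the CR pool) and miR-183-5p (2.24-fold), whose cluster partner miR-182-5p stood at 1.01-fold, miR-30d-3p (2.59-fold), the cholesterol regulator miR-33-5p (2.41-fold), miR-429-3p (2.31-fold), the erythroid miR-451a (2.30-fold), the hypoxia-induced miR-210-3p (2.29-fold) and the abundant miR-22-3p (2.16-fold, 6045 and 13062 RPM). Several of these rest on few reads, with 95% exact intervals that reach below 2-fold. They were 1.42 to 4.27 for miR-33-5p (19 and 61 reads) and 1.48 to 3.70 for miR-429-3p (27 and 83 reads). Lower in the CR pool were miR-881-3p (7.56-fold, 51 and 9 reads), miR-1948-5p (3.66-fold), miR-331-3p (3.08-fold) and miR-34a-5p, with a log2 ratio of -1.58 (95% exact interval -2.02 to -1.15).

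The ratios printed for single miRNAs are plain ratios of RPM, whereas the counts, medians, other scalings and ranking by size add 1 RPM to each level. Of 243 miRNAs with at least 10 RPM in a pool, 10 were at least 2-fold higher and 17 at least 2-fold lower in the CR pool on this scale, against 13 and 19 with nothing added. The split was 17 higher and 7 lower with DESeq2 size factors or TMM factors and 17 and 8 with upper quartile factors, and the median log2 ratio moved from -0.22 to 0.05, 0.04 and 0.01. The remaining lower miRNAs named by size were miR-574-3p (2.82-fold), miR-671-3p (log2 ratio -1.49), miR-149-5p (2.67-fold), miR-335-3p (2.38-fold), miR-1839-3p (2.40-fold) and miR-497a-5p (2.29-fold). Among abundant miRNAs, miR-21a-5p had a log2 ratio of -1.01 (190493 and 94378 RPM), miR-148a-3p of 0.88 and miR-122-5p of 0.05. With 1 pool per diet these ratios compare 2 libraries, not the diets, and have no replicate check.

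The list medians in whole liver were set against 10000 random lists of the same size, matched on mean expression. The let-7 family lay highest, with a median log2 ratio of 0.14 at the percentile 95.8, followed by the lipid and glucose list (0.05, percentile 90.7) and the miR-29 family (0.31, percentile 90.4). The list of miRNAs reported in mitochondria lay lowest (-0.50, percentile 5.28). The hepatocyte list stood at percentile 77.8, stellate cells at 64.4, ageing at 62.9, bile duct epithelium at 60.0, miR-30 at 38.7, miR-181 at 29.6, miR-10 relatives at 23.4, miR-17-92 at 22.3, leukocytes at 19.8, Dlk1-Dio3 at 19.0 and endothelium at 14.3.

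Diet ratios in the pools and in mitochondria went together in part. Over 243 miRNAs, which are not independent replicates, Pearson's r was 0.45 (permutation p = 1e-05, the smallest that the permutations can give) and Spearman's rho 0.24 (permutation p = 0.00014). Without the miR-802 arms r was 0.28. The sign was shared by 63.0% of miRNAs, and by 53.9% after each median was subtracted. miR-802-5p rose in mitochondria and was higher in the CR pool, whereas miR-199a-3p, at -1.64 in mitochondria, had a pool log2 ratio of -0.24 (95% exact interval -0.31 to -0.17).

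**Figure D2:**
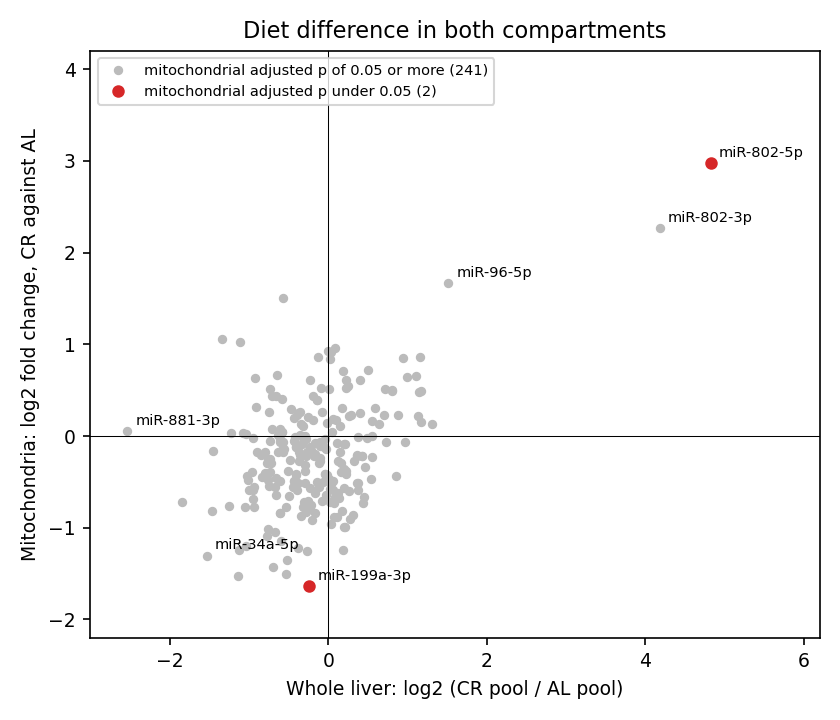
Each point is 1 of 243 miRNAs, with the log2 ratio of the CR over the AL whole-liver pool (RPM plus 1) on the x axis and the mitochondrial log2 fold change of CR against AL on the y axis. Red marks the 2 miRNAs past an adjusted p of 0.05 in mitochondria: miR-802-5p lies at the upper right and miR-199a-3p at the bottom, near 0 on the x axis.

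The interaction of diet and fraction asked whether the diet difference itself differs between mitochondria and whole liver. No miRNA passed by limma (0 of 417, with 5 at an unadjusted p under 0.05), nor by edgeR, limma-voom or DESeq2 (0 each, with 9, 12 and 8 at an unadjusted p under 0.05). miR-199a-3p was among the 5 smallest p, at -1.40 (SE 0.63, 95% interval -2.73 to -0.06, adjusted p = 0.998). The others were novel_368 (-3.27), miR-881-3p (2.59), the lymphocyte miRNA miR-150-5p (2.14) and miR-5126 (2.29). In the AL and CR pools novel_368 had 0 and 13 reads, miR-5126 6 and 1, and miR-881-3p 51 and 9. In the mitochondrial libraries novel_368 had 1 to 5 reads. CR replicate 2 held 116 reads of miR-150-5p and 78 of miR-881-3p, against 18 to 27 and 14 to 28 in the other mitochondrial libraries. In simulated data with 200 miRNAs changed at once, this test recovered 1.81% of 2-fold, 11.8% of 4-fold and 34.0% of 8-fold differences. Even 8-fold differences were thus mostly missed, and the absence of calls says little about differences up to that size. The spread of the pools was taken from the mitochondrial libraries.

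Mitochondria were set against whole liver to see which miRNAs stand out in the organelle. The mitochondrial libraries were richest, relative to whole liver, in miR-6481, let-7g-3p, miR-146a-5p, miR-193a-3p and miR-192-3p, and poorest in miR-221-5p, the unannotated novel_78, miR-744-5p, miR-361-3p and miR-872-5p. miR-146a-5p stood at 6597 ± 3512 RPM (SD, n = 6) in mitochondria against 630 RPM (AL) and 390 RPM (CR) in the pools, an 11.6-fold difference as fitted. miR-6481, whose sequence is found in the mitochondrial phenylalanine tRNA gene mt-Tf, had 730 reads in mitochondria and 3 in the pools, a 185-fold ratio of levels with a 95% counting interval of 63.2 to 901. AL replicate 2 held 420 of these reads, and without it the ratio was 92.3 (31.3 to 450), while the fit on log2(RPM + 1) gave 40.3-fold. miR-221-5p was 28.3-fold lower as fitted, at 2.04 ± 1.71 RPM (SD, n = 6) against 73.2 and 73.1 RPM.

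By limma, 134 of 417 miRNAs passed, 44 higher and 90 lower in mitochondria, with 173 at an unadjusted p under 0.05. All 134 went the same way in both diets, which calling them on the mean over both diets favours, against 82.0% of all 417. The split was 59 higher and 72 lower with TMM factors, 62 and 72 with DESeq2 size factors, 52 and 72 with upper quartile factors, and 65 and 63 with miR-122 left out. The median log2 fold change moved from -0.31 to -0.10, -0.08, -0.15 and -0.02. Under all 4 of these scalings 107 calls were kept, 44 higher and 63 lower, and none of the 134 changed sign. The limma fit of 6 against 2 libraries assumes that the pools vary like the mitochondrial libraries, and pooling and RNA preparation coincide with the fraction in every library.

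The largest higher values after miR-6481 (log2 fold change 5.33, SE 0.59) were those of let-7g-3p, with 23.9 ± 8.68 RPM (SD, n = 6) against 2 reads in each pool, miR-146a-5p (3.54, SE 0.33), miR-193a-3p (3.15), miR-192-3p (3.08), miR-29a-5p (3.01), the unannotated novel_192 (2.87), miR-500-3p (2.73) and miR-10b-5p (2.50). Another unannotated name, novel_315, had 49 reads in mitochondria and 0 in the pools, at least 12.4-fold higher against a floor of 3 reads over both pools, and its call was lost with no filter on low values (adjusted p = 0.0509). The largest lower values were miR-221-5p (-4.82, SE 0.56), novel_78 (-4.65), miR-744-5p (-4.56), miR-361-3p (-4.49, SE 0.45), miR-872-5p (-4.38), miR-335-3p (-3.64), miR-484 (-3.42), miR-340-3p (-3.29), miR-224-5p (-3.17) and miR-598-3p (-3.15). All 20 but novel_315 kept their call in every alternative that tested them. Nuclear tRNAs were not searched for matches to any of these names, the unannotated ones included. The hairpins of miR-146a (chromosome 11, 43374397 to 43374461) and miR-221 (chromosome X, 19146294 to 19146388) have no annotated gene around them on the same strand, and that of let-7g lies in an intron of Wdr82 (chromosome 9, 106178840 to 106178927, all GRCm38). miR-10b-5p has the near-identical name miR-10a-5p.

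The 5 most abundant miRNAs of AL mitochondria did not pass between mitochondria and whole liver. let-7g-5p, the opposite arm of let-7g-3p, was lower in mitochondria (-1.98, SE 0.40), at 10181 RPM on average against 34626 and 40482 RPM in the pools. miR-122-5p had a log2 fold change of 0.70 (adjusted p = 0.251), miR-21a-5p -1.01 (0.0608), miR-192-5p -0.73 (0.176), miR-148a-3p -0.46 (0.418) and miR-30a-5p -0.06 (0.921), and none of these 5 passed.

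**Figure D3:**
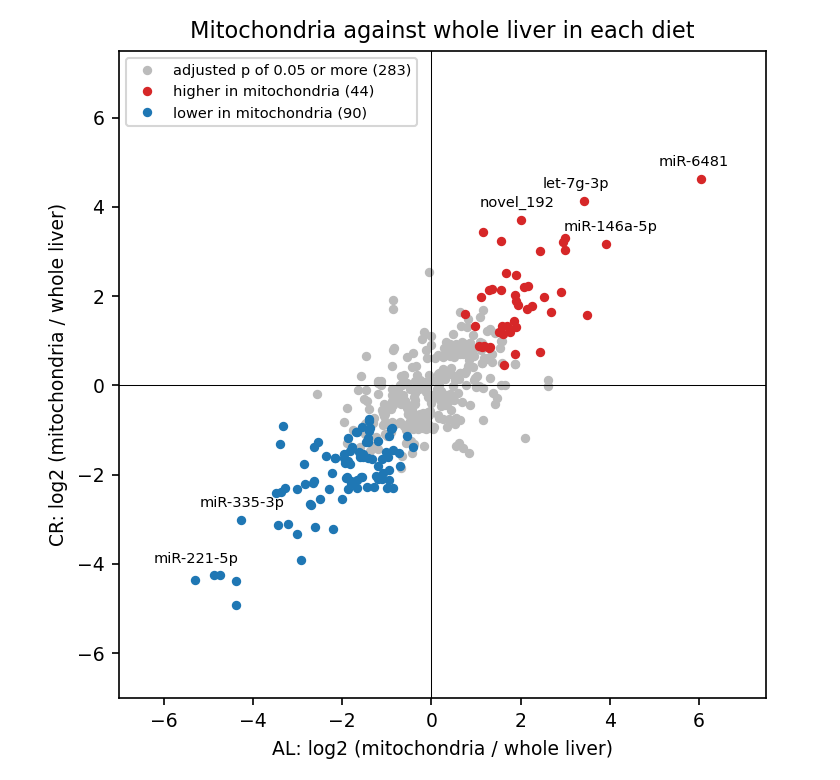
Each point is 1 of 417 miRNAs, with its log2 ratio of mitochondria over whole liver (RPM plus 1) under AL on the x axis and under CR on the y axis. The 44 miRNAs called higher (red) and the 90 called lower (blue) lie on the same side of 0 in both diets, which calling them on the mean over both favours; of the 44 and 90, 44 and 63 were kept under all 4 other scalings.

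The difference from whole liver mostly went the same way in the 2 diets, which rest on separate libraries. Across the 417 miRNAs, which are not independent replicates, Pearson's r between the AL and the CR log2 ratios was 0.83 and Spearman's rho 0.79. The sign was shared by 82.0%, and by 79.1% after each median was subtracted.

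No list as a whole passed camera between mitochondria and whole liver (0 of 18 lists, 2 at an unadjusted p under 0.05, 0 with an estimated correlation), whereas fry, which does not compare a list with other miRNAs, called 4 (the ageing and miR-29 lists upward, the miR-181 family and the miR-10 relatives downward). Calls counted as kept held in the same direction under all 4 other scalings. In the ageing list 5 of 16 members were higher (miR-146a-5p, miR-22-3p, miR-29a-5p, miR-29b-3p and miR-29c-3p), 5 also adjusted over the list alone and 5 kept (adjusted p = 0.194, and 0.572 with an estimated correlation). Its 3 miR-29 members were also the 3 of 7 that were higher in the miR-29 family (3 over the list alone, 3 kept, adjusted p = 0.194). Among miRNAs that earlier work has named in mitochondria, 3 of 22 were higher, namely miR-146a-5p, miR-378a-3p (log2 fold change 2.14) and miR-130a-5p (2.02), 1 was lower (miR-671-3p, -2.12) and 18 did not pass, with the same counts over the list alone and all 4 kept (adjusted p = 0.528). In the lipid and glucose list 5 of 24 were higher, among them miR-143-3p (1.48) and miR-378a-3p, and 4 were lower, among them miR-27b-3p (-1.96) and miR-103-3p (-1.22). Over that list alone 5 were higher and 5 lower, and 5 and 2 were kept (adjusted p = 0.528).

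Several families were split between their arms or members. In the let-7 family 7 of 19 were lower, all of them 5p arms, and 2 were higher, the 3p arms let-7g-3p and miR-98-3p (2.20), with 7 and 2 also over the list alone, and 3 and 2 kept (adjusted p = 0.528). Of 13 miR-10, miR-99 and miR-100 relatives 5 were lower, such as miR-125b-5p (-2.69) and miR-99a-5p (-2.31), and miR-10b-5p was higher, with 5 and 1 over the list alone and 4 and 1 kept (adjusted p = 0.528). In the miR-17-92 clusters 6 of 16 were lower, such as miR-20a-5p (-2.67) and miR-25-3p (-2.10), and miR-19b-3p was higher (1.90), with 6 and 2 over the list alone and 6 and 1 kept (adjusted p = 0.528). Of 6 miR-181 members 3 were lower (4 over the list alone, 1 kept, adjusted p = 0.528). In the miR-30 family 3 of 11 were lower, among them miR-30c-2-3p (-2.88), and miR-30d-3p was higher (1.04), with 3 and 2 over the list alone and 3 and 1 kept (adjusted p = 0.593). In the Dlk1-Dio3 region 2 of 17 were lower and 1 higher (2 and 0 over the list alone, 1 and 1 kept, adjusted p = 0.528).

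Markers of the liver's cell types differed member by member. Hepatocyte miRNAs had 4 of 16 lower, such as miR-194-2-3p (-1.99) and miR-455-3p (-1.78), and miR-192-3p higher, all 5 also over the list alone and kept (adjusted p = 0.795). In the stellate cell list miR-199a-5p (-1.59), miR-145a-3p (-1.42) and miR-145a-5p (-1.25) were lower and miR-143-3p higher among 9, with 4 and 1 over the list alone and 2 and 1 kept (adjusted p = 0.593). Of 9 leukocyte members miR-146a-5p alone was higher (1 over the list alone, 1 kept), while the other 8 did not pass, among them miR-155-5p (-1.28), miR-142a-5p (-0.93), miR-223-3p (-0.71), miR-142a-3p (0.46), miR-342-3p (0.31) and miR-146a-3p (0.79) (adjusted p = 0.528). Bile duct epithelial miR-200b-3p (-2.79) and miR-200a-3p (-0.91) were lower among 7 (2 over the list alone, 1 kept, adjusted p = 0.528). Endothelial miR-126a-3p (-1.08) and miR-126b-5p (-1.12) were lower among 4 (2 over the list alone, 0 kept, adjusted p = 0.528), and neuronal miR-128-3p (-1.52) among 3 (1 over the list alone, 0 kept, adjusted p = 0.593). None of 5 muscle and 6 erythroid members passed by limma, also when adjusted over the list alone (adjusted p = 0.528 for each list), with 0 members of either at an unadjusted p under 0.05. The hepatocyte list had a negative mean and median with an upward camera direction, and the lipid and glucose and leukocyte lists had negative medians with positive means.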

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

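These alternatives were chosen only after the data were seen: TMM scaling of RPM, edgeR with TMM, robust moderation in limma, the 100-read minimum, pool ratios with nothing added and antisense names left out. All others were planned.

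In mitochondria, the 2 diet calls became 5 with DESeq2 size factors, 6 with upper quartile factors, 4 with miR-122 left out, 10 with no filter, 5 with at least 50 reads, 10 with DESeq2, 5 with limma-voom, and in edgeR 5 with TMM, 6 with DESeq2 size factors, 6 with upper quartile factors, 6 with library size alone and 7 without robust moderation. TMM scaling of RPM gave 5, limma with robust moderation 1 and pseudocounts of 0.1 or 10 gave 2 each. The cause was not tested. Leaving out 1 library gave 0 to 6 calls by limma: 6 without AL replicate 1, 0 without AL 2, CR 1 or CR 2 (43, 50 and 55 at an unadjusted p under 0.05, no other tool run) and 1 without AL 3 or CR 3. In these leave-outs the log2 fold change was 2.39 to 3.71 for miR-802-5p and -1.78 to -1.51 for miR-199a-3p. Of the diet values of single named miRNAs under all alternatives, 493 kept direction and side of the threshold, 60 passed it newly, 11 fell short of it and 16 changed sign (miR-30a-5p, miR-122-5p and miR-148a-3p). miR-30a-5p changed sign to 0.17 (DESeq2 size factors), 0.14 (TMM), 0.069 (miR-122 left out), 0.26 (DESeq2), 0.11 (voom), and in edgeR 0.21 (TMM), 0.26 (DESeq2 size factors), 0.20 (upper quartile), 0.088 (library size) and 0.21 (robust moderation off), and ranged from -0.55 to 0.21 over the leave-outs. miR-122-5p ranged from -0.18 to 0.42 and miR-148a-3p from -0.079 to 0.45 over the leave-outs. The miR-122 share difference ranged from -2.38 to 14.1 points, and the cause was not tested.

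A replicate block gave 3 calls, the same 2 plus miR-146a-5p. The labels do not say whether the numbers pair the samples. Residual correlations of same-numbered libraries were 0.364, 0.075 and 0.107, and those of differently numbered ones -0.291 to 0.215. AL replicate 2 correlated best with CR replicate 3, so these values do not settle the pairing.

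Against whole liver, 454 named values kept direction and side, and 1 (novel_315, no filter) fell short. The 134 calls became 57 with AL alone and 76 with CR alone, which rest on 3 libraries against 1 pool assumed to vary like them, and 111 to 140 over the leave-outs. The interaction gave 129 calls with no filter, of which 125 had 0 reads in all 6 mitochondrial libraries and so no spread there, and 0 under every other alternative. In whole liver the 27 ratios (RPM plus 1) became 32 with nothing added, 50 with a minimum of 10 reads and 5 with 1000 reads, and the minimum sets how many miRNAs enter. With the diet, 1 list became 0 with an estimated correlation, DESeq2 size factors, TMM or the most abundant arms by camera, and 0 to 2 over the leave-outs (0 without AL 1, AL 3, CR 2 or CR 3, and 2 without CR 1, with let-7 added). Without AL 2 the 1 list was let-7. fry called 1 list with the diet and 4 against whole liver. Depth limits what was seen of rare miRNAs, with 3 reads worth 0.925 to 2.80 RPM.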

Other observations

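The tests of the miR-122 share for miR-802-5p, of hairpin arms and of antisense names were chosen only after the result was seen.

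In mitochondria against whole liver, miR-192-3p was higher (log2 fold change 3.08) while miR-192-5p did not pass (-0.73), and let-7g-3p was higher while let-7g-5p was lower (-1.98). miR-30d-3p was higher (1.04) and miR-30d-5p lower (-1.80), whereas both arms were lower for miR-455, miR-145a and miR-27b, though the calls of miR-145a-5p and miR-27b-5p were lost under 1 or more of the 4 other scalings. No test over all hairpins was made here. Of the miR-183 cluster, miR-96-5p, miR-183-5p and miR-182-5p stood at 2.97-fold, 2.24-fold and 1.01-fold in the CR over the AL pool, with mitochondrial diet log2 fold changes of 1.67, 0.86 and 0.83, none past the threshold. miR-150-5p stood at 73.5 RPM in CR replicate 2 and at 12.7 to 25.2 RPM in the other 5 mitochondrial libraries.

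miR-802-5p rose in CR mitochondria by 2.97 on the log2 scale. The read share of miR-122 as the whole cause is argued against by the value with miR-122 left out of the totals, 3.13 (95% interval 2.16 to 4.11, adjusted p = 0.000198 by limma). Carry-over of the whole-liver level into the mitochondrial preparation may account for the rise, since the CR over AL ratio of the pools was larger, 4.91. It stays open together with a diet effect on mitochondrial miR-802-5p itself, and the levels (59.4 RPM in AL mitochondria against 15.6 in the AL pool, 366 against 470 under CR) do not part them. Of the 10 splits of the 6 libraries 1, the real one, gave 2 calls, the highest other gave 0, and 10 splits are too few for a share under 0.05.

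Of the 134 miRNAs that differed between mitochondria and whole liver, 122 (91.0%) were kept in the same direction after the GC trend of each library was removed, which also removes a common shift. After all libraries were thinned to 1070762 reads, 121 were kept (median of 5 draws, 117 to 127). Neither GC content nor the deeper pools can thus be the whole cause. Pooling and RNA preparation coincide with the fraction and cannot be told apart from it.

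Some names antisense to each other held near-equal reads, such as 15243 for miR-24-3p and 14874 for miR-3074-5p, and 19560 for miR-126a-5p and 19559 for miR-126b-3p. Of 17 antisense pairs with at least 20 reads in both names, 10 (58.8%) had totals within 5%, which would follow from reads counted on both strands. Other pairs were far apart, such as 150391 for miR-126a-3p and 1248 for miR-126b-5p. Such counting thus does not describe every pair found. Pairs were found by sequence with up to 1 mismatch, not by position, so some of them may not lie opposite each other in the genome. For example, miR-30f (1580 reads) paired with both miR-30a-3p (14116) and miR-30e-3p (2825). Independent RNAs at similar levels are argued against by 4 pairs, miR-1a-3p with miR-1b-5p, miR-142a-3p with miR-142b, miR-129-5p with miR-129b-3p and miR-338-3p with miR-3065-5p, that had identical reads in all 8 libraries, as did 0 of 368 neighbours in abundance. The 10 names left out as copies held 0.314% of the reads, and the diet calls stayed at 2 without them. No other biological explanation was tested.

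A hypothesis was that a hairpin precursor changes with the diet, so that both arms move together in mitochondria. Over 112 hairpins, which are not independent replicates, Pearson's r between the arms was 0.34 (permutation p = 0.00034) and Spearman's rho 0.18 (permutation p = 0.061), with the same sign in 56.2%. Without the miR-802 and miR-199a hairpins r was 0.17 (permutation p = 0.07), so the relation rests on these and the hypothesis stays open.

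The 1 list called with the diet gave a similar question of chance. Of the 10 splits of the 6 libraries 8 gave at least 1 list, the highest other gave 3, and 10 splits are too few for a share under 0.05.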
